A study of Streptococcus gordonii with 8 samples.

How the data were processed

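Total RNA was taken from 8 *S. gordonii* samples, 4 exposed for 30 min to defined medium with 5 mM arginine and 4 to medium without it. Per the labels' protocols, 50 ng of RNA was amplified and labelled with a single dye, and RNA quality was monitored by the submitters. No quality values were used here. Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.7.3.1. Per the file headers, the processed intensity of each spot was background-subtracted and spatially detrended, and was not scaled between arrays. The deposited scanner files also give the median pixel intensity of each spot and of its local background. The authors' value table for the series is on a log2 scale, which was found by comparison because its units are not given in the sources used here. After a constant per probe and a constant per array were removed, its values differed from the log2 processed intensities by at most 1.95e-06, for 2049 probes, and 60 further entries were controls. Its column medians were 0.0291, 0.0202, -0.0131 and -0.0621 for with-arginine replicates 1 to 4 and 0.00246, 0.0524, 0.0135 and 0.0134 for without-arginine replicates 1 to 4. Direction and scale were thereby settled, while the baseline each probe was centred on stays unknown.

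Control spots and spots that the scanner software marked as outliers (2.02% to 3.59% of the organism's spots per array) were left out. Saturated spots would have been kept, but there were 0. The main values were log2 processed intensity minus the 75th percentile of the same array, and the 6 spots of a probe were averaged. Every coding sequence had 1 probe. A probe counted as above background on an array if over 0.5 of its spots were marked well above background, and the 2013 probes above background on at least 4 of the 8 arrays were tested, which left out 36. Averages and scaling mean that all changes are relative to the bulk of the transcripts: a shift common to all transcripts would be removed. Fold changes of dim signals depend on the background correction. Residual background would compress them toward 1, and subtracting too much would inflate them. Which of these applies was not tested. With normexp, whose offset itself lowers ratios, all 4 sequences and 13 regions described with their changes moved less.

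The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without minus with arginine, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 6 residual degrees of freedom, and the prior added 4.62. Run and permutation statistics used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Probes were ordered by the chromosome coordinates in their feature names (*S. gordonii* chromosome sequence, version 1, 1-based as written there), where a prefix marks the complement strand. A run was at least 4 adjacent tested sequences that all passed in one direction, compared with 10000 random orders. The SE of a run's change comes from the 4 array means per group. Data were simulated with the real levels and spreads of 2013 sequences. Of 50 planted changes of each log2 size, 2% were recovered at 0.5, 18% at 1, 72% at 2 and 94% at 4, and 7% of calls were false. Small changes were thus mostly missed in this simulation, where 1813 of the 2013 sequences were unchanged. The adjustment is less strict when more sequences change. Recovery in the real data, where 696 passed, may therefore be higher and was not measured. In a separate random order of calls, 10 runs planted as sequences that had already passed were all found. That checks only the search for runs, and the power to detect real blocks was not measured.

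The rule for single sequences, fixed before the data were examined, was the 10 largest increases and the 10 largest decreases among those whose groups did not overlap, together with members of gene lists and of runs. Because the files do not pair probes with names, only the leading 2 in each direction are described singly, with the isolated sequence among the 10 largest increases added after its values were seen. The rule for regions, the 6 runs with the largest mean increase and the 6 with the largest mean decrease, was also chosen after seeing the data. For the same reason the 27 gene lists planned for pathway tests were not matched to probes, and those tests were not run. Runs were planned on locus tags and were made on coordinates instead. Other settings fixed in advance were background correction by normexp (offset 50), centring on the median, quantile normalization, no filter or a stricter filter on dim probes, an intensity trend with robust variances, the replicate number or the slide as a block, the authors' value table, and leaving out each array in turn. The column of mean pixel signals planned for normexp was not used here, and median signals took its place. Scaling on 7 added control transcripts, keeping the spots marked as outliers, fits within each slide, and ending runs at a strand change were added after seeing the data. Cultures were split between the media, but no label ties a replicate number to a culture, so the groups were compared without pairing.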

Results

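*Streptococcus gordonii* is an early coloniser of the tooth surface, and its mRNA levels were measured here on one-colour oligonucleotide arrays after cells had spent 30 min in a chemically defined medium with 5 mM arginine or in the same medium lacking it. Mid-exponential cultures were divided before this exposure. The labels describe the 4 samples of each group as biological replicates, which gave 8 arrays in all. Each array carried 12830 spots, of which 12294 held probes for 2049 coding sequences, at 6 spots per sequence. Between 97.0% and 99.0% of these spots lay well above background on each array, and 0 were saturated. The 75th percentile of the processed signal ranged from 3390 to 18629 intensity units, and levels are given below as log2 signal relative to that percentile of the same array. The small number of arrays limits the precision. The files do not pair the probes with gene names or products, so coding sequences are described by their start, end and strand on the chromosome sequence the array was designed from, and each region named below consists of coding sequences and the gaps between them. The lengths of all 2048 sequences with a complete name were multiples of 3 bases, as reading frames are.

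The comparison asked which transcripts responded to the removal of arginine. Whole blocks of adjacent coding sequences rose or fell together. One of the steepest rises was in a block of 7 on the minus strand between 1616579 and 1622366, whose mean level climbed from -3.70 ± 0.53 with arginine to 1.96 ± 0.51 without it (SD, n = 4 per group), a mean change of 5.66 (SE 0.37) or 50.7-fold. A block of 4 at 692644 to 695382 rose by 5.34, and it was the higher of these blocks with normexp background correction (5.24 against 5.20), without without-arginine replicate 1 (5.79 against 5.58) and within slide 2 (6.01 against 5.65). The steepest fall was in a block of 8 on the minus strand between 1629852 and 1637350, which dropped from 2.01 ± 0.06 to -2.91 ± 0.58 (SD, n = 4 per group), a mean change of -4.92 (SE 0.29) or 30.3-fold. Across the chromosome, 696 of the 2013 coding sequences tested with limma changed at an adjusted p under 0.05, of which 347 were higher and 349 lower without arginine. A measured change of at least 2-fold was passed by 627 of them, 305 higher and 322 lower. Measured log2 changes of over 4 were seen in 21 sequences that rose and 9 that fell, and changes of over 3 in 41 that rose and 50 that fell. These counts include 3 sequences that rose and were not well above background on any array with arginine, for which only a lower bound of the change can be given. At those bounds 304 rose at least 2-fold, 20 by over 4 and 39 by over 3.

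**Figure D1:**
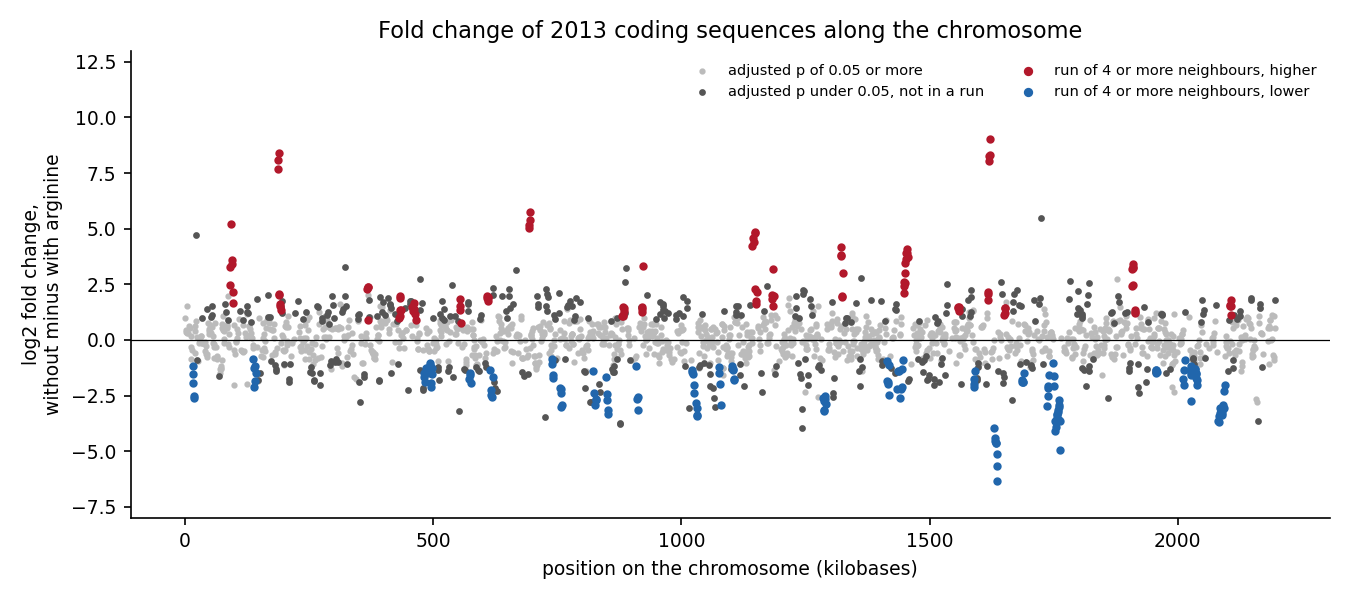
Log2 fold change (without minus with arginine) of each of the 2013 tested coding sequences against its position in kilobases. Red and blue points are members of the 47 runs of at least 4 adjacent sequences that passed the test in one direction, dark grey points passed it outside runs, and pale grey points did not pass. The tallest red columns reach 9.02 and 8.42, and the lowest blue point lies at -6.36.

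The sequence at 1621344 to 1622366 on the minus strand (1023 bases) was one of those with the largest increases. Its level was -7.50 ± 0.46 with arginine and 1.51 ± 0.21 without it (SD, n = 4 per group), a log2 change of 9.02 (SE 0.30, limma adjusted p = 1.16e-08) or 519-fold, against 7.69 or 207-fold with normexp. A very short coding sequence of 96 bases at 188724 to 188819 on the plus strand rose by 8.42 (SE 0.40, limma adjusted p = 1.71e-07) or 341-fold, from -5.20 ± 0.54 to 3.21 ± 0.67 (SD, n = 4 per group). The order of these sequences turned with normexp, where the latter rose by 7.99 or 255-fold, and within slide 1 (9.05 against 8.63). The sequences with the largest decreases over all 8 arrays were neighbours inside the most strongly lowered block, while within slide 1 the sequence at 1762648 to 1763439 had the lowest change (-5.46 against -5.34) of those that passed. The one at 1635586 to 1635825 (240 bases, minus strand) went from 1.67 ± 0.36 to -4.69 ± 0.99 (SD, n = 4 per group), a change of -6.36 (SE 0.46, limma adjusted p = 5.42e-06) or 82.2-fold, against -5.65 or 50.2-fold with normexp. The one at 1635161 to 1635475 (315 bases, minus strand) went from 2.08 ± 0.40 to -3.60 ± 1.07 (SD, n = 4 per group), a change of -5.68 (SE 0.49, limma adjusted p = 1.75e-05). All 4 of these sequences were well above background on all 8 arrays. That the groups did not overlap in them was a condition of the rule that picked them. Of the 10 largest increases, 4 lay in the block at 1616579 to 1622366, 3 in a block at 186069 to 192723, 2 in a block at 692644 to 695382, and 1 was an isolated sequence of 1647 bases at 1723341 to 1724987. Of the 10 largest decreases, 8 were the block at 1629852 to 1637350 and 2 belonged to a block at 1748104 to 1763439.

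In total, 285 coding sequences, 40.9% of those that changed, lay in 47 runs of at least 4 adjacent members that passed the test in the same direction. Of these runs, 19 were higher without arginine (114 sequences) and 28 were lower (171 sequences), and 40 had all members on a single strand. Random orders of the same 2013 sequences placed 12.3 in such runs on average and 47 at most (10000 orders, permutation p = 0.0001, one-sided, the smallest these orders can give). In 45 of the 47 runs the mean levels of the 4 arrays of one group all lay on one side of those of the other. This is not separate support for the runs, since all their members had passed the test on these same arrays.

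Among the blocks that rose, the change was often uneven and stepped at particular positions. In the block at 1616579 to 1622366, the 4 sequences from 1618239 to 1622366 rose by 8.02 to 9.02, whereas the 3 adjoining ones from 1616579 to 1617758 rose by 1.80 to 2.17. In the block of 8 at 186069 to 192723 on the plus strand, the 3 sequences from 186069 to 188819 rose by 7.70 to 8.42, and the 5 that followed rose by 1.37 to 2.07. Here the mean change was 4.09 (SE 0.19). The 9 sequences at 1142924 to 1153679 on the plus strand rose by 3.41 on average (SE 0.19), with 4.22 to 4.85 for the 5 up to position 1148185 and 1.59 to 2.29 for the 4 beyond it. By contrast, the 4 minus-strand sequences at 692644 to 695382 rose evenly, by 5.01 to 5.75 (mean 5.34, SE 0.48). A block of 11 minus-strand sequences at 1447747 to 1456054 rose by 2.12 to 4.08 (mean 3.22, SE 0.18). In the block of 6 at 1320929 to 1324862 on the minus strand, the sequence at 1322055 to 1322354 was not well above background on any array with arginine. It was at least 7.70-fold higher without arginine (limma adjusted p = 0.00201 for the measured change, not for this bound). The bound sets the mean of the without-arginine arrays against a value for each with-arginine array. That value is the higher of the sequence's own signal and the lowest signal among probes well above background. The other 5 members of this block rose by 1.93 to 3.83. A run of 7 at 89598 to 97452, 5 of them on the plus strand, is described after its values were seen, because it also held a sequence that was not well above background on any array with arginine. That sequence, at 93748 to 94485, was at least 6.18-fold higher without arginine by the same kind of bound (limma adjusted p = 0.000756 for the measured change). The other 6 rose by 1.66 to 5.19. With these sequences at their bounds the mean changes were 2.97 for the run at 89598 to 97452 and 2.91 for the block at 1320929 to 1324862, the reverse of their order by measured means (3.11 and 3.12). The remaining 12 runs that rose held 62 sequences, with mean changes from 1.24 to 2.42.

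Among the blocks that fell, all 8 sequences at 1629852 to 1637350 had log2 changes of -3.97 to -6.36. The longest run of all held 18 sequences at 1748104 to 1763439, 16 of them on the minus strand, with a mean change of -3.20 (SE 0.22) and single changes from -1.06 to -4.95. A run of 14 minus-strand sequences at 2080914 to 2095117 had a mean change of -3.10 (SE 0.28), with members from -2.02 to -3.70. The 7 minus-strand sequences at 1283517 to 1292242 changed by -2.83 on average (SE 0.44), and the plus-strand runs of 5 at 848405 to 853307 and of 5 at 755181 to 759680 changed by -2.66 (SE 0.39) and -2.54 (SE 0.46). The remaining 22 runs that fell held 114 sequences, with mean changes from -1.31 to -2.41. With normexp the mean change was -1.82 for the run at 755181 to 759680, 2.27 for the one at 1320929 to 1324862 and 2.49 for the one at 89598 to 97452.

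**Figure D2:**
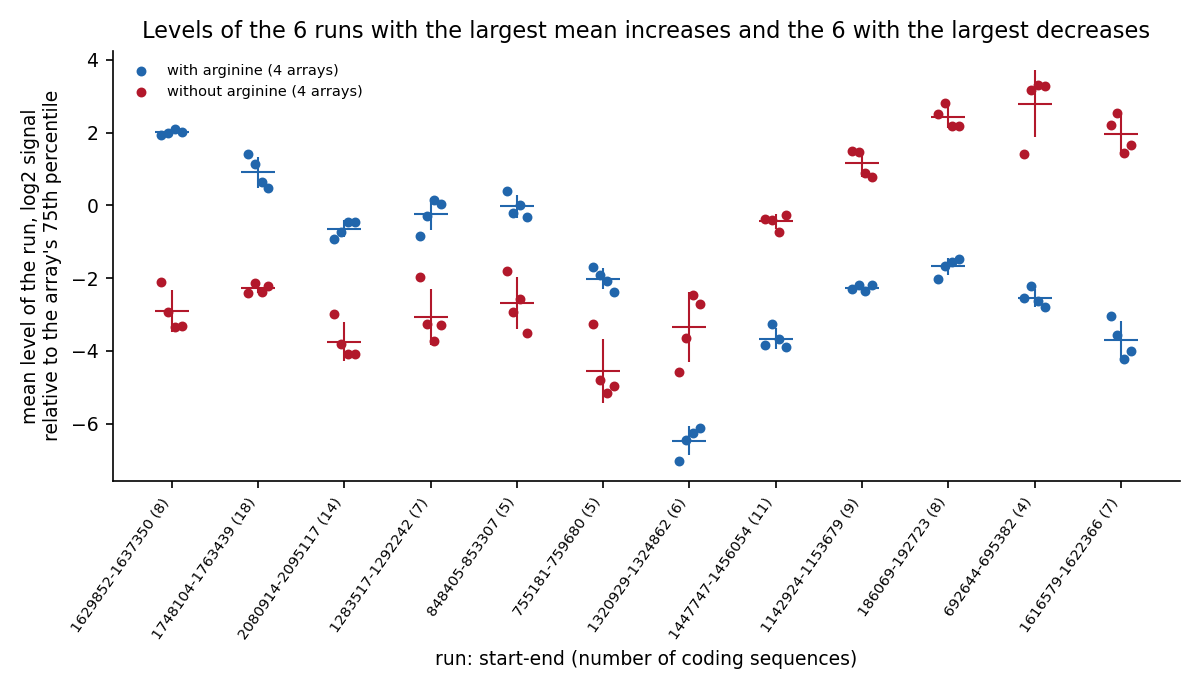
Mean level of each of the 6 runs with the largest mean increases and the 6 with the largest mean decreases by measured means, in log2 signal relative to the array's 75th percentile, for the 4 arrays with arginine (blue points) and the 4 without (red points). Horizontal strokes are group means and vertical bars are ± 1 SD, and the run at 1320929 to 1324862 includes a member that was not well above background with arginine. In all 12 runs, whose members had each passed the test on these same arrays, the groups do not overlap. In the run at 692644 to 695382 without-arginine replicate 1 lies at 1.41 while the other arrays of its group lie between 3.16 and 3.31.

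Close neighbours on the same strand responded alike. For 846 pairs of neighbours on the same strand and under 50 bases apart, the log2 changes correlated at Pearson r = 0.931 and Spearman rho = 0.898 across pairs, and 225 of the 226 pairs in which both members passed the test moved the same way. With 50 to 199 bases between same-strand neighbours, r was 0.626 and rho 0.487 (533 pairs), and at 200 bases or more r was 0.251 and rho 0.262 (281 pairs). Neighbours on opposite strands had r = 0.140 and rho = 0.112 (352 pairs). Of pairs in which both members passed the test, 85 of 99, 32 of 44 and 31 of 43 moved the same way in these 3 kinds, so that same-strand neighbours at 200 bases or more (72.7%) and neighbours on opposite strands (72.1%) gave similar shares, whose difference was not tested. Permutation p-values of r over pairs, two-sided, were 0.0001 (the smallest possible), 0.0001, 0.0002 and 0.0085 for these 4 kinds of pair (0.0002, 0.0002, 0.000267 and 0.0085 after Benjamini-Hochberg adjustment over the 4), and coding sequences are not independent replicates. The 846 closest pairs also correlated, at r = 0.820, in the deviation of with-arginine replicate 1 from its group mates, where the medium was the same. Likeness of close neighbours, which random orders break up, was thus not limited to the arginine response.

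The groups did not overlap in 588 of the 696 changed sequences. Over all 2013 sequences the share without overlap was 33.9%, where chance gives 2.86%. Arrays came from 2 slides, each with 2 arrays of each group. With slide as a block 796 sequences passed, and within a slide (2 arrays against 2) 218 passed on slide 1 and 831 on slide 2. Over all 2013 sequences 74.2% had the same sign on both slides, and log2 changes of all sequences correlated between slides at Pearson r = 0.728 and Spearman rho = 0.658. The balance of increases and decreases rests on the scaling: relative to added control RNA, 247 sequences passed, 62 higher and 185 lower (25.1% higher, against 49.9%), and the median change of all sequences was -0.24 in place of 0.06. The array percentile relative to that control RNA was 0.376 ± 0.768 with arginine and 0.0739 ± 0.714 without it (log2, SD, n = 4 per group), which did not differ by more than the spread between arrays (exact permutation p = 0.543, two-sided).

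Taken over the sequences that rose or fell, the response was weaker on without-arginine replicate 1 than on its mates, but blocks differed. This array had the weakest response of its group at 692644 to 695382 (1.41 against 3.16 to 3.31) and at 1629852 to 1637350 (-2.09 against -3.34 to -2.92). It was not weaker at 1142924 to 1153679 (1.48 against 0.79 to 1.46) or at 1748104 to 1763439 (-2.42 against -2.37 to -2.13), where it lay close to its nearest mate. At 1142924 to 1153679 the without-arginine arrays of slide 1 (1.48 and 1.46) lay above those of slide 2 (0.89 and 0.79). A response score, the mean level of the sequences that rose minus that of those that fell in a fit made without the array in question, lay between -2.39 and -2.07 on the 4 arrays with arginine, at -0.24 on without-arginine replicate 1, and between 1.76 and 2.64 on the other arrays without arginine. The first principal component (62.7% of the variance) separated the groups, with without-arginine replicate 1 nearest to the other group at 14.1. The second (19.2%) set with-arginine replicate 1, at 39.6, apart from the other arrays.

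**Figure D3:**
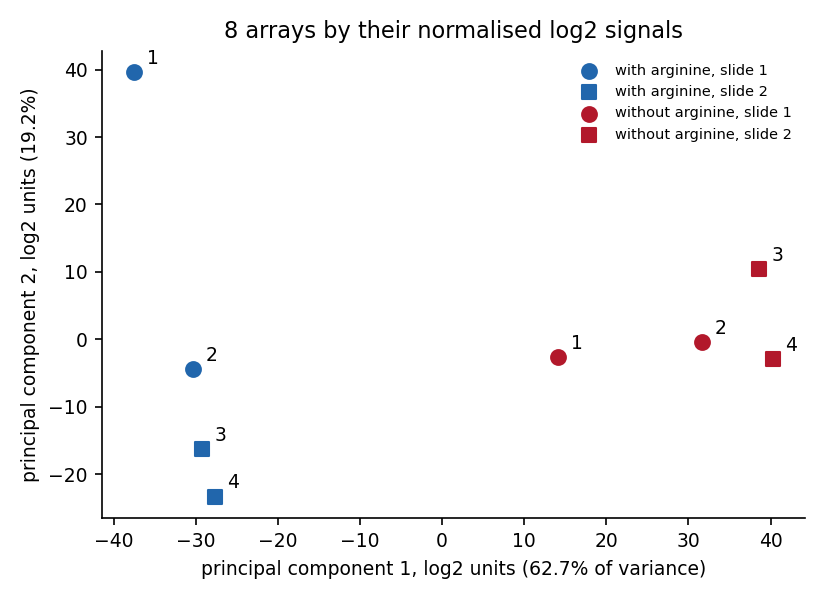
The 8 arrays on the first 2 principal components of the normalised log2 signals, in log2 units, coloured by group, with slide as the marker and the replicate number beside each point. With-arginine arrays lie between -37.5 and -27.7 on the first component and without-arginine arrays between 14.1 and 40.3.

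On with-arginine replicate 1, 20 coding sequences stood over 4 log2 units (16-fold) above the mean of its 3 group mates, against at most 1 on any other array. They fell into 10 places on the chromosome. The largest held 7 adjacent minus-strand sequences at 1988946 to 1992651, with a mean level of 1.94 on this array and -7.50 on its mates. At 123957 to 124130 the excess was 10.55 on the log2 scale, or 1497-fold. None of the 20 passed the test for arginine (0 at limma adjusted p under 0.05). They could hardly have passed, because the excess on this array widens the spread of its group. Against the other 3 with-arginine arrays alone, their mean levels without arginine differed by -1.40 to 2.75 on the log2 scale.

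**Figure D4:**
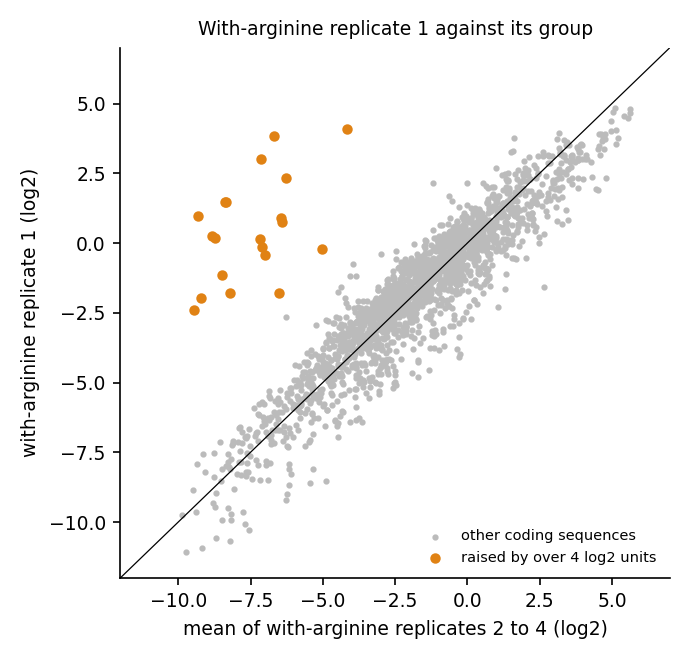
Level of each tested coding sequence on with-arginine replicate 1 against the mean of with-arginine replicates 2 to 4, both in log2 signal relative to the array's 75th percentile, with the line of equal levels. The 20 orange points lie over 4 log2 units above the mean of the group mates.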

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

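For with-arginine replicate 1, the tests of spot noise and of RNA from another sample were chosen only after the result was seen. In groups of 4 arrays, the highest or lowest array was compared with the spacing of the others for 44 groups of values, 4 of which stood out, where chance alone gives about 1 in 20.

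With-arginine replicate 1 had 119 sequences over 2 log2 units from the mean of its mates, against 23 to 30 on the other arrays of its group. Over all sequences, the deviation correlated at r = 0.820 between 846 pairs of same-strand neighbours under 50 bases apart (permutation p = 0.0001, the smallest possible). This value covers far more than the 20 most raised and cannot decide about them. These 20 were not scattered spot errors, since the 6 spots of a raised probe had a median SD of 0.0576 and at most 0.0985. RNA of an arginine-free sample is argued against because the same sequences were only 0.858 higher (median log2) without arginine than on the other 3 with-arginine arrays. High brightness of the array is argued against because the brightest array of the other group showed a median deviation of 0.0407 at these sequences. A different state of that culture, or RNA or DNA from a source outside these samples, may be behind it; the design holds no group that sets this culture apart, so no biological explanation was tested.

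Without-arginine replicate 1 had the lowest mean level of the run at 692644 to 695382, 1.41 against 3.16 to 3.31 on its mates. Without-arginine replicate 2 had a 75th percentile 0.990 log2 units below the added control RNA (-0.990), where its mates lay 0.328 to 0.523 above it. The median signal of without-arginine replicate 3 was 5917 intensity units, against 979 to 1591 on its mates. Of 40 kinds of control probe, 7 served for the scaling on added control RNA. Among the others, 6 had over 0.5 of their spots well above background on without-arginine replicate 3 and on no array with arginine. Their log2 signals were not scaled between arrays, and 23 of the 40 kinds were brighter on this array than on any with arginine. The 6 were the spike-in probe (+)E1A_r60_a104 at 7.46, the probe (+)eQC-40 at 6.08, and the probes ETG07_105829 at 6.29, ETG08_142674 at 5.35, ETG10_234183 at 7.46 and ETG10_236652 at 5.57, where the highest values with arginine were 3.46, 4.12, 3.43, 2.62, 2.61 and 3.40.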

How the results depend on the processing

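The spike-in, within-slide, outlier-spot and strand-change settings were chosen only after the results were seen. Across the settings fixed in advance other than leaving out arrays, 663 to 796 sequences changed (696 as reported), 587 to 673 changed at least 2-fold (627) and 272 to 341 lay in runs (285). Leaving out each array in turn gave 480 to 784, 465 to 700 and 202 to 342. The 4 sequences described singly with their levels and the 13 regions with mean changes kept their direction in all 21 settings, at 0.719 to 1.28 times the reported log2 value. Much of this was fixed beforehand, since nearly all were picked as the largest changes on these same arrays. The filters, variance settings and blocks hardly alter a fold change in this design (9.02 at 1621344 to 1622366 under each). Median centring, the authors' values and control RNA shift the changes of all sequences by a common amount. Changes by over 1.5-fold came with normexp (7.69, -5.65, -1.82, 2.27 and 2.49, given above) and within slides: 9.05 on slide 1 and 7.78 on slide 2 at 188724 to 188819, -5.34 and -7.38 at 1635586 to 1635825, -4.55 and -6.81 at 1635161 to 1635475, 4.66 and 6.01 at 692644 to 695382, and -2.05 and -3.61 at 1283517 to 1292242. Of the 696, 1 had the opposite sign under normexp and 0 under each other setting. Keeping outlier-marked spots gave 692, and ending runs at a strand change 264. Scaling on added control RNA gave 247 changed, 247 at least 2-fold and 116 in runs; that RNA varied between arrays of a group, and whether its amounts or the mRNA content differed was not tested. Fits within a slide have fewer samples (2 arrays against 2 on each). The values were 218, 218 and 97 within slide 1 and 831, 825 and 353 within slide 2. Slide 1 held with-arginine replicate 1 and without-arginine replicate 1, each of which stood apart from its group as described above. Leaving these out of the full fit, singly, raised the count from 696 to 784 and 768. Leaving out any other array lowered it, to between 480 and 593. These arrays may thus account for part of the low count on slide 1. Why the slides differ was not tested. With the replicate number as a block 713 sequences changed, but the numbers were not shown to pair the samples: same-numbered arrays correlated at -0.0210, 0.376, 0.0796 and 0.257 in their deviations from group means, and 4 of 8 arrays correlated best with their own number. Of the 35 splits of the 8 arrays into 4 and 4, 1 (the real one) gave counts as large as 696, 627 and 285. The highest of the others, the split by slide, gave 6 and 6, and 0 in runs. The smallest share that 35 splits can give is 1 in 35. Each other split also places the group difference in its within-group spread, so low counts there were likely beforehand. This comparison therefore cannot exclude chance as the source of the counts. A single probe per sequence left nothing to compare for the brightest-probe setting, and the gene list settings were not run. Signal over background limits 36 sequences that were left out and 3 that were above background on no array with arginine.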

Other observations

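The tests of the size of the response along stretches, of chance order in the decline, of distance from the chromosome start and of coding strand, and leaving out the steepest stretch, were chosen only after the results were seen; the other tests below were chosen before their outcome.

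Besides the blocks, responses differed with coding strand. Taking position 1 as the replication origin and the far side of the chromosome (last position 2196625) as the terminus, which was assumed and not measured, 415 sequences are read toward the origin and 1598 away from it. Of the former, 97 rose and 32 fell, and of the latter 250 rose and 317 fell. The median log2 change was 0.38 for sequences read toward the origin and -0.06 for those read away from it, a difference of 0.44 (circular-shift permutation p = 0.000497, the smallest that 2013 shifts can give). It was 0.32 on slide 1 and 0.56 on slide 2, and 0.49, 0.36 and 0.43 in short, middle and long sequences. Distance from position 1 had no such relation (Spearman rho = -0.00110 across sequences). More downstream members of closely spaced stretches on one strand is argued against, because the difference was 0.469 among the 723 sequences with no same-strand neighbour under 50 bases away. A candidate explanation is that genes on the 2 strands differ in function or in their coupling to replication; with no gene names neither was tested.

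A hypothesis that responses shrink toward the end of stretches of at least 4 closely spaced same-strand sequences was not borne out: over 38 responding stretches the mean slope of the size of the change had a sign-flip permutation p of 0.618. Stretches that rose and stretches that fell went opposite ways, and a new hypothesis was made from that and tested on the same data: the signed log2 change declines in the direction of transcription. It declined in 81 of 97 stretches, by a mean of -0.23 per member (SD 0.29, sign-flip permutation p = 1e-05, the smallest possible), and in 51 of the 59 stretches with a mean change under 2-fold. All stretches were measured on the same arrays and are not independent replicates. Sign-flip p-values over stretches therefore do not measure the spread between samples. Within single arrays, the mean slope of the level per member was 0.12 ± 0.01 with arginine and -0.11 ± 0.06 without it (SD, n = 4 per group, exact permutation p = 0.0286, two-sided, the smallest 4 against 4 can give). On slide 1 it was 0.12 and 0.11 with arginine against -0.04 and -0.09 without, and on slide 2 it was 0.13 and 0.12 against -0.18 and -0.14. The difference between the groups (-0.23) restates the mean decline already seen over the same 97 stretches. Its direction and size were therefore known beforehand, and only the spread between arrays was new.

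Dim probes are argued against as the whole source of this decline, since in 26 stretches of bright members only the mean slope was -0.19 (sign-flip permutation p = 0.00434), with a decline in 18 of them. The stretch at 188724 to 190952, a step from 8.42 to 2.07 with a slope of -2.05, weighs heavily there: without it the mean slope of the other 25 was -0.11 (sign-flip permutation p = 0.00803), and that of all other 96 stretches was -0.21. Coding length and signal level are argued against, since the mean slope after removing both trends was -0.233. RNA integrity and the labelling reaction were not tested and stay open. Transcription that reaches the downstream part of a stretch less often without arginine may account for the pattern, as a hypothesis; coverage along single transcripts would test it.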
